A study of Homo sapiens with 9 samples.

How the data were processed

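RNA of MG-63 cells, a human osteosarcoma line used as a model of osteoblasts, was sequenced from 3 groups of 3 libraries. The groups were bare Ti6Al4V, Ti6Al4V with TiB2 (titanium diboride by its formula) and boronized Ti6Al4V with HA, called here bare alloy, TiB2 and HA coating. Per the labels' protocols, cells were cultured for 7 days in medium with 10 mM beta-glycerophosphate, 50 µg/mL ascorbic acid and 100 nM dexamethasone, and total RNA was extracted with TRIzol and prepared with a NEBNext Ultra RNA kit. The labels gave all 9 libraries the same batch and stated that the TiB2 libraries were left out of the final analysis. They did not state whether libraries of one group came from separate cultures.

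The authors deposited, in a single table, 36385 Ensembl genes, each with a raw count and an FPKM value per library. The submitters' processing notes named cutadapt 2.10, HISAT2 2.2.1, StringTie 2.1.4, featureCounts 2.0.1, limma and the GRCh38 build, without saying which step each tool did. The deposited FPKM values followed the deposited counts: the ratio of FPKM to count within a gene had a median SD of 0.00087 on the log2 scale over 13401 genes, apart from 1 factor per library. Of the deposited counts between 1 and 20, 55.5% were even. Strand use and the treatment of reads that map to several places are not given in the sources used here, so genes with near-identical copies (CXCL1, CXCL2 and CXCL3, HSPA1A and HSPA1B, the RN7SL and RNA5-8S genes), overlapping genes and antisense genes are uncertain. Only an identifier was given for 9638 rows, and 333 rows shared a symbol with an earlier row. GENCODE release 29 held 34442 of the identifiers (94.7%), and coordinates are those of the deposited table.

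Groups and replicate numbers came from the sample labels. The plan fixed before the data were examined had limma on log2(FPKM + 1) as the main test, with edgeR in its place if the table held raw counts, so edgeR is the main test here and limma on FPKM an alternative. Each comparison used only its own 6 libraries. Genes were kept by edgeR's filterByExpr, library sizes scaled by TMM, and the 2 groups compared with the quasi-likelihood test (glmQLFit, glmQLFTest; edgeR 4.0.16, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM (counts scaled to library size) after TMM scaling over all 9 libraries, as mean ± SD. Other tools were limma 3.58.1, DESeq2 1.42.0, data.table (1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

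The 35 gene lists, fixed before the data were examined, were osteoblast differentiation, osteocyte and mineral regulation, BMP and TGF-beta response, Wnt targets and regulators, fibrillar and network collagens, collagen processing, matrix glycoproteins and proteoglycans, matrix proteases and inhibitors, integrins and focal adhesion, SRF and YAP targets, cell cycle genes of G2 and M phase, cell cycle genes of G1 and S phase, p53 targets and apoptosis, NF-kB and inflammatory genes, interferon-stimulated genes, hypoxia and glycolysis, ATF4 and unfolded protein response, NRF2 and oxidative stress, metallothioneins and metal transport, heat shock proteins, cholesterol synthesis, glucocorticoid response, immediate early and MAPK feedback genes, the Notch pathway, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, replication-dependent histones, nuclear and intron-retaining long RNAs, and markers of osteoclasts and macrophages, adipocytes, chondrocytes, epithelium, endothelium and muscle. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. For each list the count of members past edgeR's threshold is given with adjustment over all genes and, where stated, adjusted over the list alone. Camera with an estimated correlation and fry were alternatives.

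Genes named in the text followed a rule fixed at the same time. For HA coating against bare alloy it took 8 osteogenic genes whatever their result (RUNX2, SP7, ALPL, BGLAP, SPP1, IBSP, COL1A1, SPARC), the 8 largest rises and 8 largest falls, and up to 3 members of each list past its test. The rises and falls had to be past the threshold, have a symbol, a mean FPKM of at least 5 in the higher group and no overlap between the 3 and 3 libraries. In the other comparisons it took the same 8 genes where they passed, 5 rises and 5 falls, and up to 2 members per list.

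Totals ranged from 58464306 to 72542556 counts per library. A count of 0 allows up to 3 counts, or 0.0414 to 0.0513 CPM in these libraries, which covers counting error only. On simulated data with known changes, the edgeR step recovered 31% of 2-fold and 94% of 4-fold changes for HA coating against bare alloy (19398 genes), 68% and 95% for TiB2 against bare alloy (19518 genes), and 34% and 91% for HA coating against TiB2 (19396 genes). The changes were placed in the better expressed genes only. In the same order, 4.6%, 7.9% and 6.7% of all calls were unchanged genes.

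Alternatives were other filters, scalings, tools and pseudocounts, 1 fit over all 9 libraries, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were a GC and length offset (per-library trends), the removal of bare alloy replicate 1 together with HA coating replicate 3, and 2 settings for a split of the libraries into sets: the set as a term over all 9 libraries, and the HA libraries against bare alloy replicate 1 alone. With the set as a term, HA coating is compared with bare alloy replicate 1, and TiB2 with bare alloy replicates 2 and 3. Other libraries enter those fits only through scaling, filtering and the estimate of spread. For HA coating against bare alloy both set settings are thus the same contrast. No deposited library was left out of the tests given first.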

Results

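The data were RNA-seq counts of MG-63 cells after 7 days in osteogenic medium on 3 surfaces: bare Ti6Al4V (bare alloy), a titanium alloy used for implants, the same alloy with TiB2, and boronized alloy with HA (HA coating). Each surface had 3 libraries, with 58464306 to 63122541 counts on bare alloy, 62951461 to 63413815 on TiB2 and 60528871 to 72542556 on the HA coating. Nothing in the labels says that libraries of one surface came from separate cultures, so p-values measure the spread between these libraries, which may be technical. No pair of libraries agreed within sampling noise: the median squared deviation between replicates was 11.9 to 16.4 times the Poisson value on bare alloy and TiB2, and 43.4 to 69.0 times on the HA coating.

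Some libraries stood apart from others of their own surface. Ribosomal DNA rows took 6.48% of the counts in bare alloy replicate 1, 1.07% and 0.617% in bare alloy replicates 2 and 3, and 0.083% to 0.197% in the 6 coated libraries. A trend with GC content and gene length accounted for 30.5% of the deviation of HA replicate 2 and 25.4% of that of HA replicate 3, and for at most 11.8% in any other library. A set of 22 genes with at least 20 counts in each library on one side and at most 3 on the other parted the 9 libraries into 4 (bare alloy replicate 1 and all 3 HA libraries) and 5 (bare alloy replicates 2 and 3 and all 3 TiB2 libraries). Of these genes 17 were detected in the 5 libraries, among them the T cell genes CD3D, CD3E and LCK, and 5 in the 4 libraries. In all 199 genes met these limits for some split: a different 22 parted HA replicate 3 alone from the rest, and 19 parted bare alloy replicate 1 alone. Among splits with at least 2 libraries on each side the next had 6 genes. Below, the 22 genes are those of the split into 4 and 5. CD3E, a chain of the T cell receptor complex, lay at 1.5 to 2.47 CPM in the 5 libraries and at 0 in the 4, where a count of 0 allows up to 0.0414 to 0.0513 CPM, while ENPEP, a membrane peptidase, lay at 1.69 to 1.86 CPM in the 4 and at 0 in the 5.

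Cells on the HA coating were compared with cells on bare alloy to ask what the boronized surface with HA does to osteogenic differentiation, the question in the title of the series. On the HA coating the inflammatory cytokine and chemokine genes were far higher: IL24, a cytokine of the IL-10 family, rose from 0.646 ± 0.011 to 93.9 ± 24.6 CPM (SD, n = 3 each), 144-fold, and CXCL8, which attracts neutrophils, rose 48.2-fold. Cell cycle genes rose too, 21 of 26 of G2 and M phase (median 1.18 on the log2 scale) and 21 of 26 of G1 and S phase (0.93), as did 15 of 23 cholesterol synthesis genes (1.07; list adjusted p = 0.169 with an estimated correlation). Of the collagens 8 of 17 fell and of other matrix genes 7 of 28, with adjusted p = 0.335 and 0.426 with an estimated correlation. COL14A1, which encodes a collagen that binds along fibrils, fell from 207 to 11.4 CPM, 18.2-fold. Of the osteoblast genes fixed in advance, ALPL rose 6.38-fold, while COL1A1 and SPARC fell 2.68-fold and 2.31-fold.

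ALPL encodes the alkaline phosphatase of bone, which frees phosphate for mineral (ENSG00000162551, GRCh38 chromosome 1, 21509397 to 21578410). It rose from 1.72 ± 0.56 to 11 ± 4.32 CPM (log2 fold change 2.67 ± 0.36, SE; edgeR adjusted p = 0.00353). COL1A1, the main chain of type I collagen (ENSG00000108821, chromosome 17, 50184101 to 50201632), fell from 3049 ± 464 to 1140 ± 644 CPM (-1.42 ± 0.37; edgeR adjusted p = 0.0446). The COL1A1 call was lost in 5 of 6 cases with 1 library left out. SPARC, a collagen-binding matrix protein of bone (ENSG00000113140, chromosome 5, 151661096 to 151686975), fell from 3994 ± 322 to 1740 ± 283 CPM (-1.21 ± 0.20; edgeR adjusted p = 0.00862). RUNX2, the transcription factor that starts the osteoblast programme (ENSG00000124813, chromosome 6, 45328157 to 45664349), lay at 2.3 ± 0.33 and 3.18 ± 0.99 CPM (0.46 ± 0.30; edgeR adjusted p = 0.353; 0.24 to 0.69 with 1 library left out). SPP1, which encodes osteopontin (ENSG00000118785, chromosome 4, 87975667 to 87983529), did not pass (0.77 ± 0.43; edgeR adjusted p = 0.280; 0.48 to 1.60 with 1 library left out): it lay at 45.9 to 49.5 CPM in the HA libraries, at 51.7 CPM in bare alloy replicate 1 and at 15.7 and 15.3 CPM in replicates 2 and 3. BGLAP, which encodes osteocalcin, had 3 to 17 counts in these 6 libraries (-0.62 ± 0.82; edgeR adjusted p = 0.670; -1.49 to -0.22 with 1 library left out). SP7, a later osteoblast transcription factor, had 24, 0 and 0 counts on bare alloy, and IBSP, a mineral-binding bone protein, had 0. Both had 0 in all 3 HA libraries. For IBSP no difference was detectable at this depth, and for SP7 all the counts came from bare alloy replicate 1. Over the whole osteoblast list 3 of 20 tested genes rose, 5 fell and 12 did not pass (3 and 7 adjusted over the list alone; median -0.64, camera adjusted p = 0.535).

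**Figure D1:**
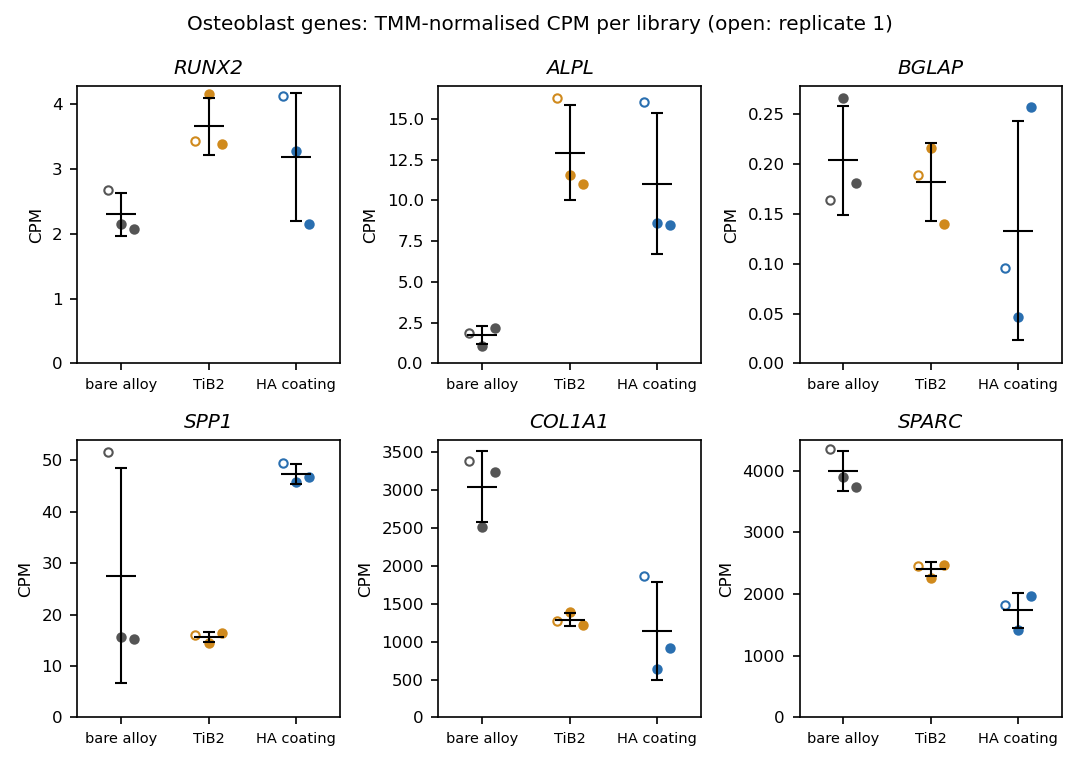
Levels of RUNX2, ALPL, BGLAP, SPP1, COL1A1 and SPARC in CPM (y axes, linear) on bare alloy, TiB2 and HA coating, 1 point per library (open for replicate 1), with bars for mean ± SD (n = 3). ALPL was higher in all 6 coated libraries than in the 3 bare alloy libraries, COL1A1 and SPARC were lower, and SPP1 parted bare alloy replicate 1 (51.7 CPM) from replicates 2 and 3.

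The 8 largest rises were IL24 (ENSG00000162892, chromosome 1, 206897443 to 206904139; log2 fold change 7.17 ± 0.26, edgeR adjusted p = 7.34e-06), CXCL10 (5.72), CXCL8 (5.59 ± 0.32, edgeR adjusted p = 5.17e-05), CXCL3 (5.28), CXCL1 (5.14), MMP1 (5.03), CXCL6 (4.85) and CXCL11 (4.49). Without HA replicate 3 CXCL10 stood at 4.59, MMP1 at 4.18 and CXCL11 at 3.45. CXCL10 and CXCL11 attract T cells, CXCL1, CXCL3 and CXCL6 attract neutrophils, and MMP1 is a collagenase. Of the NF-kB and inflammatory list 22 of 30 tested genes rose, none fell and 8 did not pass (25 up and 1 down adjusted over the list alone; median 2.11). The list passed camera (adjusted p = 3.6e-55; adjusted p = 0.0178 with an estimated correlation), and its mean level was 2.2 log2 units higher in the lowest coated library than in the highest bare alloy library. Ranked by fold, 3 of the 8 largest falls were copies of the signal recognition particle RNA, RN7SL5P (-5.24), RN7SL2 (-5.00) and RN7SL4P (-4.77), for which bare alloy replicate 1 stood apart: RN7SL2 lay at 211 CPM there and at 10.0 and 5.75 CPM in replicates 2 and 3. Without that library RN7SL5P stood at -2.08 and lost its call, RN7SL2 at -1.74 and RN7SL4P at -1.97. Each of these 3 lost its call without any 1 of the HA libraries (edgeR adjusted p = 0.0685 to 0.139). The other falls were MYOC, which encodes the secreted protein myocilin (-4.70 ± 0.19, edgeR adjusted p = 7.34e-06), COL14A1 (-4.19 ± 0.23, edgeR adjusted p = 5.17e-05), OLFM2 (-4.01), ITGBL1 (-3.71) and CCN4, a secreted Wnt target (-3.50).

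Cell division genes were higher. Of the G2 and M phase list 21 of 26 rose and none fell (25 up adjusted over the list alone), with AURKA, a mitotic kinase, 2.56-fold higher, BUB1, a spindle checkpoint kinase, 2.39-fold, and KIF2C 2.38-fold. The G2 and M phase list had camera adjusted p = 1.37e-27 (adjusted p = 0.0178 with an estimated correlation). Of the G1 and S phase list 21 of 26 rose and none fell (26 up adjusted over the list alone), with CDC45 (2.5-fold), CCNE2 (2.32-fold) and CDC6 (2.27-fold), which act in the start of DNA replication. The G1 and S phase list had camera adjusted p = 2.53e-19 (adjusted p = 0.0412 with an estimated correlation). Cholesterol synthesis genes also rose, 15 of 23 with none down (18 adjusted over the list alone): HMGCS1, the synthase of HMG-CoA, rose 5.11-fold (2.35 ± 0.22), FDPS 3.40-fold and MVK 3.12-fold. The cholesterol list had camera adjusted p = 3.31e-18 (adjusted p = 0.169 with an estimated correlation).

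Stress and metabolic lists moved by smaller amounts. NRF2 and oxidative stress genes had 8 of 22 up and none down (13 adjusted over the list alone), among them PGD (2.14-fold) and NQO1 (2.13-fold), which make or use NADPH, and TKT (1.69-fold). The NRF2 list had camera adjusted p = 4.66e-06 (adjusted p = 0.335 with an estimated correlation). In the hypoxia and glycolysis list 5 of 27 rose (13 adjusted over the list alone), among them ALDOC (2.66-fold), PFKFB4 (2.23-fold) and PGK1 (2.02-fold), all enzymes of glycolysis or its control. The hypoxia list had camera adjusted p = 0.00039 (adjusted p = 0.491 with an estimated correlation). ATF4 targets had 6 of 27 up and 1 down (8 and 2 adjusted over the list alone), with ATF3 2.25-fold, TRIB3 2.03-fold and MTHFD2 1.66-fold higher. The ATF4 list had camera adjusted p = 0.021 (adjusted p = 0.491 with an estimated correlation). That call was lost without HA replicate 1 (camera adjusted p = 0.0752) or HA replicate 3 (0.061). p53 targets had 4 of 22 up and 1 down by either adjustment, with PMAIP1 (2.74-fold) and FAS (1.97-fold), which promote apoptosis, and AEN (1.84-fold). The p53 list had camera adjusted p = 0.026 (adjusted p = 0.335 with an estimated correlation). Heat shock proteins had 3 of 17 up (4 adjusted over the list alone), the mitochondrial chaperonins HSPE1 (2.02-fold) and HSPD1 (1.92-fold) and HSPH1 (1.64-fold). The heat shock list had camera adjusted p = 0.00636 (adjusted p = 0.491 with an estimated correlation). With a mean FPKM of at least 5, which tests fewer members, the calls of hypoxia (median 0.40, against 0.66 in the main test; camera adjusted p = 0.145), ATF4 (0.15 against 0.26; 0.427), heat shock (0.33 against 0.45; 0.0757) and p53 (0.24 against 0.22; 0.454) were lost. Without HA replicate 3 the hypoxia median was 0.35, with its call kept, and the ATF4 median 0.15. With limma on log2(FPKM + 0.1) the calls of ATF4 (0.20; 0.0662) and p53 (0.22; 0.0721) were lost. With 1 library left out HSPE1 lost its call in 5 of 6 cases, AEN, ALDOC, HSPD1, HSPH1, MTHFD2 and TRIB3 in 4 each, ATF3, NQO1, PGK1, PMAIP1 and TKT in 3 each, and FAS, PFKFB4 and PGD in 2 each. Camera also called 3 lists upward that had no single member past edgeR's threshold by either adjustment: nuclear-encoded oxidative phosphorylation (26 genes, median 0.59, camera adjusted p = 2.03e-05), cytosolic ribosomal proteins (32 genes, 0.44, 0.00636) and mitochondrially encoded genes (15 genes, 0.39, 0.0081). With an estimated correlation these had adjusted p = 0.491, 0.626 and 0.491, and without HA replicate 3 the ribosomal median was 0.06 (camera adjusted p = 0.457) and that of oxidative phosphorylation 0.29, with its call kept. Under the GC and length offset the ribosomal call was lost (median 0.12, camera adjusted p = 0.222), as was the mitochondrial one (0.07, 0.714), while oxidative phosphorylation kept its call at 0.33. With a mean FPKM of at least 5 the ribosomal (0.31, 0.0945) and mitochondrial (0.28, 0.134) calls were lost. With the library set as a term the mitochondrial call (0.22, camera adjusted p = 0.417) and the heat shock call (0.29, 0.0929) were lost. Against bare alloy replicate 1 alone, the same contrast for this comparison, both calls were lost as well, with medians of 0.25 and 0.31. The p53 list missed the threshold there (0.054) with a larger median, 0.35 against 0.22.

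Some matrix genes fell, and the lists of collagens, glycoproteins and collagen processing passed camera downward, though not with an estimated correlation. Of the collagens 8 of 17 fell and none rose (12 down adjusted over the list alone, median -0.98). COL5A3 was 7.65-fold and COL5A2 2.53-fold lower, both chains of type V collagen. The collagen list had camera adjusted p = 1.26e-14 (adjusted p = 0.335 with an estimated correlation). Matrix glycoproteins and proteoglycans had 7 of 28 down and 1 up (10 and 3 adjusted over the list alone; median -0.63): THBS2, an anti-angiogenic matrix protein, fell 4.53-fold, FBLN2 4.15-fold and POSTN, the periosteal matrix protein periostin, 1.92-fold. The matrix glycoprotein list had camera adjusted p = 9.96e-06 (adjusted p = 0.426 with an estimated correlation). Collagen processing genes had 6 of 22 down (9 adjusted over the list alone), including ADAMTS14 (3.05-fold) and PCOLCE (2.34-fold), which act in removing procollagen ends, and the crosslinking enzyme LOXL1 (2.41-fold). The collagen processing list had camera adjusted p = 0.00012 (adjusted p = 0.491 with an estimated correlation). The BMP and TGF-beta list had 7 of 26 down and 2 up (9 and 2 adjusted over the list alone; median -0.56). Its named members were extracellular BMP regulators, CHRDL1 (3.37-fold lower), BMPER (3.67-fold lower) and GREM1 (2.01-fold higher). The BMP list had camera adjusted p = 0.00495 (adjusted p = 0.426 with an estimated correlation). Wnt genes had 3 of 25 down and 1 up (5 and 1 adjusted over the list alone), with CCN4 11.3-fold and WNT5B 2.40-fold lower and WNT7B 3.73-fold higher. The Wnt list had camera adjusted p = 0.0467 (adjusted p = 0.470 with an estimated correlation). Integrins and focal adhesion genes had 4 of 26 down and 1 up (4 and 2 adjusted over the list alone): the collagen receptor chains ITGA11 (4.51-fold) and ITGA1 (2.41-fold) were lower and ITGA2, another collagen receptor chain, 2.60-fold higher. The integrin list had camera adjusted p = 0.0284 (adjusted p = 0.546 with an estimated correlation). The Wnt call was lost without HA replicate 2 (camera adjusted p = 0.0683), and the integrin call without HA replicate 2 (0.122) or HA replicate 3 (0.105). Both missed the threshold under the GC and length offset (camera adjusted p = 0.158 and 0.16), with medians of -0.24 (Wnt) and -0.14 (integrins) against -0.20 each in the main test. They missed it against bare alloy replicate 1 alone, with medians of -0.09 and -0.20. With the library set as a term, the same contrast here, the Wnt list missed it (-0.12, camera adjusted p = 0.0683). Replication-dependent histones had 2 of 8 down, H2BC21 (3.21-fold) and H2AC6 (2.48-fold), and 3 adjusted over the list alone. The histone list had a median of -0.98 and camera adjusted p = 0.000685 (adjusted p = 0.342 with an estimated correlation). Its mean log2 level was 2.83 in bare alloy replicate 1, the library with 6.48% ribosomal DNA counts, and 2.02 and 2.01 in replicates 2 and 3. Without replicate 1 the median was -0.58 (camera adjusted p = 0.0036), and without HA replicate 3 it was -1.53. Of the genes named in this paragraph, with 1 library left out LOXL1 lost its call in 3 of 6 cases, PCOLCE and WNT5B in 2 each, and GREM1, POSTN and WNT7B in 1 each. Without HA replicate 3 the collagen processing median was -0.55 (main -0.31), and without HA replicate 1 the Wnt median was -0.44.

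**Figure D2:**
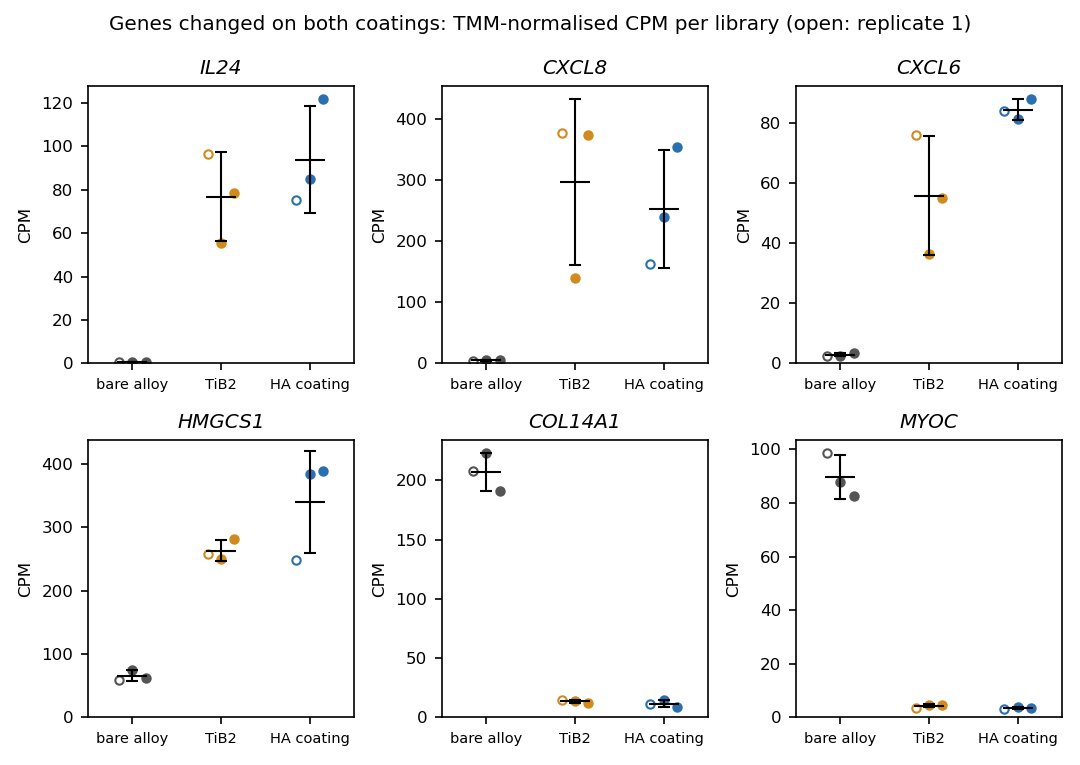
Levels of IL24, CXCL8, CXCL6, HMGCS1, COL14A1 and MYOC in CPM (y axes, linear) on the 3 surfaces, 1 point per library (open for replicate 1), with bars for mean ± SD (n = 3). The first 4 genes were higher and the last 2 lower in all 6 coated libraries than in the 3 bare alloy libraries, with IL24 at 0.646 CPM on bare alloy and 93.9 CPM on the HA coating.

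The remaining lists did not pass camera. Osteocyte and mineral genes had 1 of 13 up and 2 down (2 and 3 adjusted over the list alone; camera adjusted p = 0.144), matrix proteases 3 of 21 up and 4 down (6 and 5; 0.843), SRF and YAP targets 1 of 23 up and 3 down (1 and 4; 0.0693), and interferon-stimulated genes 1 of 29 up and 4 down (3 and 4; 0.0637). Metallothioneins and metal transport had 2 of 16 up (camera adjusted p = 0.194), glucocorticoid response 2 of 19 up (0.129), immediate early genes 4 of 24 up and 1 down (0.0812), the Notch pathway 1 of 19 up and 2 down (0.496), and nuclear long RNAs 1 of 10 up and 2 down (0.332). Among markers of other cell types, the camera adjusted p was 0.331 for osteoclasts and macrophages (1 of 8 up), 0.622 for adipocytes (1 of 9 up), 0.110 for chondrocytes (2 of 10 down), 0.908 for epithelium (0 of 9 past edgeR's threshold), 0.517 for endothelium (1 of 9 up, 2 down) and 0.494 for muscle (1 of 7 down).

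In all, edgeR called 1990 of 20117 genes (9.9%), 1009 higher and 981 lower, 5488 at an unadjusted p under 0.05, and camera called 19 lists, of which 3 also passed with an estimated correlation. The count without 1 library ran from 598 (without bare alloy replicate 2) and 601 (replicate 3) through 857 (bare alloy replicate 1) and 1092 (HA replicate 2) to 4185 (HA replicate 1), and 35 of the 61 named calls were kept in all 6 cases. COL1A1 lost its call in 5 of them (edgeR adjusted p = 0.0989 to 0.145), and SPARC (0.0517) and POSTN (0.0514) without bare alloy replicate 2. The HA libraries and bare alloy replicate 1 were on the same side of the 22 genes above. With the library set as a term over all 9 libraries edgeR called 704 genes, 647 of them shared with the 1990. For this comparison that term leaves bare alloy replicate 1 as the only control. A fit against that replicate alone tests the same contrast, with the spread taken from the HA libraries. Against that replicate alone ALPL (2.56, edgeR adjusted p = 0.0291), IL24, CXCL8, COL14A1 and HMGCS1 were among the 24 of 61 named calls that stayed past the threshold, while COL1A1 (-1.56, edgeR adjusted p = 0.206), SPARC (-1.31, 0.174) and the named cell cycle genes did not. The cell cycle lists kept their size and call there, with medians of 1.20 for G2 and M phase (camera adjusted p = 5.56e-17) and 1.04 for G1 and S phase (2.42e-14).

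TiB2 was compared with bare alloy in the libraries that the labels leave out of the final analysis; no purpose was stated for it. Cytokine genes led here too: IL24 rose 118-fold, from 0.646 ± 0.011 to 76.8 ± 20.4 CPM (SD, n = 3 each), and CXCL8 rose 57.0-fold. HMGCS1 rose 3.98-fold (log2 fold change 1.99 ± 0.10, SE), and ALPL 7.51-fold (2.91 ± 0.27). POSTN fell 8.84-fold (-3.15 ± 0.09) and COL14A1 15.4-fold (-3.94 ± 0.10), and interferon-stimulated genes, which act against viruses, were lower in 27 of 29 cases, by a median of -0.83 (list adjusted p = 0.195 with an estimated correlation).

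Among the fixed genes, ALPL reached 12.9 ± 2.89 CPM (edgeR adjusted p = 8.45e-05) and RUNX2 3.65 ± 0.44 CPM (0.67 ± 0.20, 1.59-fold; edgeR adjusted p = 0.0373). COL1A1 fell to 1292 ± 87.8 CPM (2.36-fold; edgeR adjusted p = 0.00014) and SPARC to 2399 ± 114 CPM (1.67-fold; edgeR adjusted p = 0.00076). The 5 largest rises were IL24 (edgeR adjusted p = 3.09e-07), CXCL8, CXCL3 (33.4-fold), SCARA5, a ferritin receptor (28.1-fold), and IL1B, an inflammatory cytokine (27.5-fold). The 5 largest falls were all small structural RNAs for which bare alloy replicate 1 stood apart: RMRP (-7.54), RNA5-8SN1 (-6.38), RNA5-8SN3 (-6.23), RN7SL1 (-5.59) and RN7SL2 (-5.52). Without that library RMRP (-1.60), RNA5-8SN1 (-0.82) and RNA5-8SN3 (-0.92) lost their calls, RN7SL1 and RN7SL2 stood at -2.04 and -2.26, and all 5 did without any 1 of the TiB2 libraries (edgeR adjusted p = 0.0542 to 0.113).

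Of the inflammatory list 26 of 30 rose and none fell, by either adjustment (median 2.06), with LIF, an IL-6 family cytokine, 5.91-fold and the superoxide dismutase SOD2 5.82-fold higher. The inflammatory list had camera adjusted p = 5.18e-46 (adjusted p = 0.0811 with an estimated correlation). All 26 genes of the G2 and M phase list rose, with BUB1B 2.27-fold and NUSAP1 1.90-fold higher. The G2 and M phase list had camera adjusted p = 5.28e-21 (adjusted p = 0.223 with an estimated correlation). Of the G1 and S phase list 23 of 26 rose (26 adjusted over the list alone), with the replication genes CDT1 2.28-fold and MCM7 1.71-fold. The G1 and S phase list had camera adjusted p = 1.82e-11 (adjusted p = 0.316 with an estimated correlation). Cholesterol synthesis genes rose in 18 of 22 cases (19 adjusted over the list alone), FDPS by 3.08-fold. The cholesterol list had camera adjusted p = 1.39e-40 (adjusted p = 0.0041 with an estimated correlation). NRF2 genes rose in 17 of 22 (18 adjusted over the list alone), PGD 3.05-fold and NQO1 2.57-fold. The NRF2 list had camera adjusted p = 1.66e-22 (adjusted p = 0.0811 with an estimated correlation). Glucocorticoid response genes had 7 of 20 up and 1 down, by either adjustment. Of these STEAP4, a metalloreductase, was 6.09-fold and NFKBIA, the inhibitor of NF-kB, 2.83-fold higher. The glucocorticoid list had camera adjusted p = 0.000123 (adjusted p = 0.0811 with an estimated correlation).

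Smaller rises were seen in 6 more lists on TiB2. ATF4 targets had 14 of 27 up and 4 down (15 and 4 adjusted over the list alone), with SLC7A11, the cystine transporter, 2.33-fold and TRIB3 2.2-fold higher. The ATF4 list had camera adjusted p = 0.000546 (adjusted p = 0.0818 with an estimated correlation). Hypoxia and glycolysis had 10 of 27 up and 1 down (11 and 2 adjusted over the list alone), with ALDOC 4.40-fold and HK2 2.56-fold. The hypoxia list had camera adjusted p = 0.000346 (adjusted p = 0.434 with an estimated correlation). p53 targets had 11 of 22 up and 1 down (12 and 1 adjusted over the list alone), with GDF15 3.65-fold and DDB2 1.61-fold. The p53 list had camera adjusted p = 0.00223 (adjusted p = 0.108 with an estimated correlation). Immediate early genes had 10 of 24 up and 4 down (12 and 4 adjusted over the list alone), with IER3 5.93-fold and ETV4 2.46-fold. The immediate early list had camera adjusted p = 0.00966 (adjusted p = 0.316 with an estimated correlation). Mitochondrially encoded genes rose in 12 of 15 cases by either adjustment, MT-ND4 by 1.75-fold and MT-ND4L by 1.64-fold. The mitochondrial list had camera adjusted p = 1.25e-06 (adjusted p = 0.356 with an estimated correlation). Nuclear-encoded oxidative phosphorylation had 6 of 26 up by either adjustment, with COX5A 1.49-fold and UQCRC2 1.26-fold. The oxidative phosphorylation list had camera adjusted p = 0.0377 (adjusted p = 0.535 with an estimated correlation). This last call was lost without bare alloy replicate 3 (camera adjusted p = 0.158), TiB2 replicate 1 (0.124) or TiB2 replicate 3 (0.0593), in 1 fit over all 9 libraries (0.123) and with the replicate block (0.0547). It missed the threshold under the GC and length offset (median 0.14, camera adjusted p = 0.0524) and, with the change as large, with the library set as a term (0.20 against 0.19 in the main test, 0.1). With a mean FPKM of at least 5, which tests fewer genes, 6 calls among the rising lists were lost: glucocorticoid (0.27, against 0.57 in the main test; camera adjusted p = 0.147), ATF4 (0.31 against 0.33; 0.0531), hypoxia (0.19 against 0.34; 0.0872), p53 (0.27 against 0.29; 0.0872), immediate early (0.19 against 0.48; 0.222) and oxidative phosphorylation (0.14; 0.17). The immediate early call was also lost with limma on log2(FPKM + 0.1) (0.45; 0.139).

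Ranked by camera adjusted p, the lists that fell on TiB2 were led by interferon-stimulated genes, 27 of 29 down by either adjustment, with IFI44L 3.95-fold and OAS3, an antiviral synthetase, 2.04-fold lower. The interferon list had camera adjusted p = 6.94e-25 (adjusted p = 0.195 with an estimated correlation). Collagens had 10 of 16 down and 1 up by either adjustment, with COL12A1 2.5-fold lower. The collagen list had camera adjusted p = 5.74e-16 (adjusted p = 0.0811 with an estimated correlation). Matrix glycoproteins had 10 of 27 down and 5 up by either adjustment, with FBLN2 2.81-fold lower. The matrix glycoprotein list had camera adjusted p = 2.56e-06 (adjusted p = 0.223 with an estimated correlation). Collagen processing had 8 of 22 down and none up by either adjustment, with ADAMTS14 2.34-fold and P4HA1, a prolyl hydroxylase, 1.56-fold lower. The collagen processing list had camera adjusted p = 0.00966 (adjusted p = 0.356 with an estimated correlation) and missed the threshold in 1 fit over all 9 libraries (0.0606) and with the library set as a term (0.0737), at medians of -0.16 and -0.17 against -0.16 in the main test. Of the BMP genes 11 of 26 fell and 4 rose (11 and 5 adjusted over the list alone), with ID4 4.96-fold and CHRDL1 2.60-fold lower. The BMP list had camera adjusted p = 0.00993 (adjusted p = 0.151 with an estimated correlation). With a mean FPKM of at least 5 it missed the threshold (0.0892) with 11 members tested and a median of -0.69, against -0.36 in the main test. Of the Wnt genes 9 of 25 fell and 3 rose (9 and 4 adjusted over the list alone), with CCN4 13.6-fold and the secreted Wnt modulator DKK2 6.50-fold lower. The Wnt list had camera adjusted p = 0.00575 (adjusted p = 0.122 with an estimated correlation). SRF and YAP targets had 9 of 22 down and 4 up (10 and 5 adjusted over the list alone), with TPM1 2.01-fold and LATS2 1.74-fold lower. The SRF and YAP list had camera adjusted p = 0.027 (adjusted p = 0.411 with an estimated correlation). That call was lost without bare alloy replicate 1 (0.0583) or TiB2 replicate 3 (0.0654), in 1 fit over all 9 libraries (0.0511), with limma on log2(FPKM + 0.1) (0.0636), and with the library set as a term (0.193), where the median was -0.15 against -0.23 in the main test. Histones had 5 of 8 down (6 adjusted over the list alone), with H2BC21 3.46-fold and H2AC6 3.22-fold lower. The histone list had a median of -1.05 and camera adjusted p = 5.16e-06 (adjusted p = 0.151 with an estimated correlation). Without bare alloy replicate 1, where both these genes and ribosomal DNA stood highest, the median was -0.77 and the call was kept. With 1 TiB2 library left out the medians of Wnt genes (-0.26 in the main test), matrix glycoproteins (-0.19) and collagen processing reached -0.12, -0.06 and -0.10, with their calls kept, and without bare alloy replicate 1 that of BMP genes was -0.23. The other 15 lists did not pass, with camera adjusted p from 0.0725 (metallothioneins and metal transport) to 0.838 (adipocyte markers); the osteoblast list had 5 of 21 up and 6 down (5 and 7 adjusted over the list alone; camera adjusted p = 0.285).

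In this comparison edgeR called 5059 of 20152 genes (25.1%), 2594 higher and 2465 lower, 7405 at an unadjusted p under 0.05, and camera called 20 lists, of which 1 also passed with an estimated correlation. All TiB2 libraries were on the same side of the 22 genes as bare alloy replicates 2 and 3, and against those alone edgeR called 4211 genes. With the library set as a term over all 9 libraries it called 1173, 1134 of them shared with the 5059. That term also compares TiB2 with bare alloy replicates 2 and 3, but takes the spread from all 9 libraries. The lower count thus does not measure an effect of the set, and all 9 libraries without the term gave 2132. With the term COL1A1 (-1.16, edgeR adjusted p = 0.0963) and SPARC (-0.67, 0.0581) were past the threshold no longer. Their fold changes matched those without bare alloy replicate 1 (-1.16 and -0.68), as the same contrast requires. The RUNX2 call was lost in 5 of the 6 cases with 1 library left out (edgeR adjusted p = 0.0624 to 0.122).

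**Figure D3:**
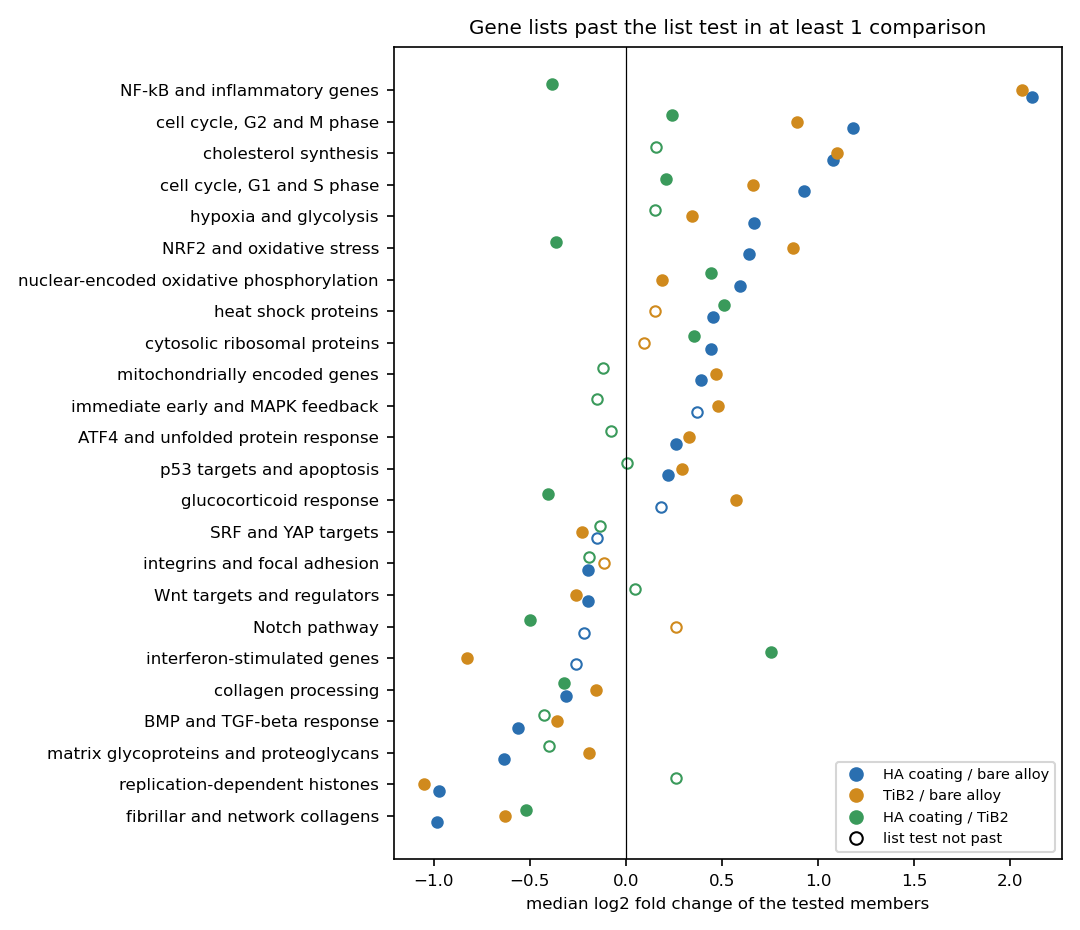
Median log2 fold change (x axis) of the tested members of each list that passed camera at a preset correlation of 0.01 in at least 1 of the 3 comparisons (colours), with open points where a list did not pass. The inflammatory list lay highest against bare alloy on both coated surfaces (2.11 and 2.06), and the interferon-stimulated list lay at -0.26 on the HA coating and -0.83 on TiB2.

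Both coated surfaces were compared with the same 3 bare alloy libraries, and their fold changes correlated across 19548 genes (r = 0.739; genes are not independent replicates). Simulated groups with no effect against those libraries gave a mean r of 0.516 (highest 0.547 of 20). The covariance was 0.515 against 0.1 simulated, a difference of 0.415. Of the called genes 834 were higher on both surfaces, where independent lists would share 129.7, and 830 lower on both, where they would share 123.7, with 1 gene called in opposite directions. With 3 controls no split leaves at least 2 libraries in each part, so part of the excess may come from the shared controls.

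**Figure D4:**
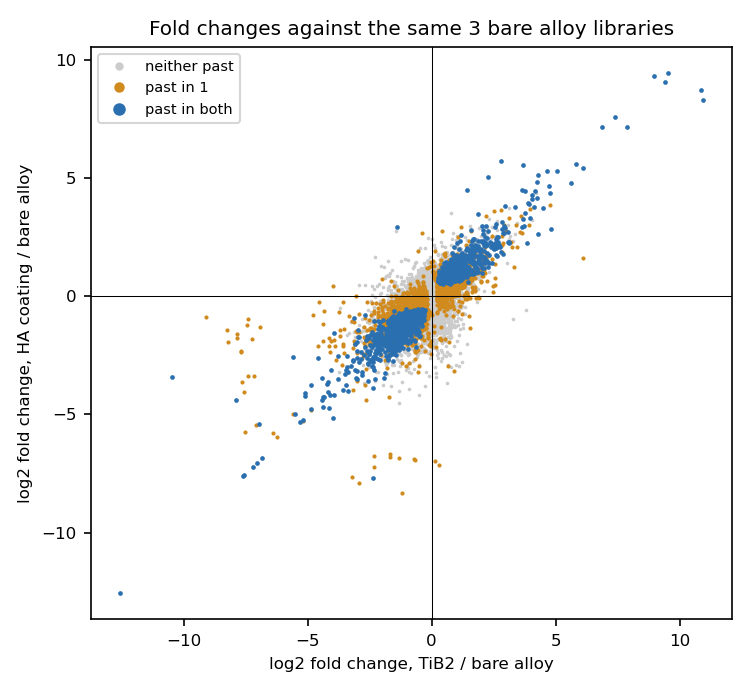
Log2 fold change of each gene on TiB2 (x axis) and on the HA coating (y axis) against the same 3 bare alloy libraries, coloured by whether edgeR called it in neither, 1 or both comparisons. Across 19548 genes r was 0.739, and shared controls alone gave a mean of 0.516 in simulations.

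The HA coating was then compared with TiB2 directly, which tests whether the responses to these boron-containing surfaces differed. SPP1 was 3.01-fold higher on the HA coating, 47.4 ± 1.90 against 15.6 ± 1.02 CPM (SD, n = 3 each), with bare alloy replicate 1 at 51.7 CPM and replicates 2 and 3 at 15.7 and 15.3 CPM. POSTN was 4.61-fold higher (log2 difference 2.2 ± 0.16, SE) and MMP1 6.86-fold higher (2.78 ± 0.49; 1.91 without HA replicate 3 and 3.10 without HA replicate 1). CITED4, a transcriptional coactivator, was 7.84-fold lower, at 2.69 against 20.9 CPM, but with the library set as a term SPP1 stood at -0.14 and CITED4 at 0.13. Interferon-stimulated genes were higher on the HA coating than on TiB2 by a median of 0.75, with none of 29 past edgeR's threshold over all genes and 20 past it adjusted over the list alone (list adjusted p = 0.683 with an estimated correlation).

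The 5 largest rises were MMP1 (edgeR adjusted p = 0.0415), PDXP, a pyridoxal phosphatase (6.62-fold; edgeR adjusted p = 0.000881), POSTN (edgeR adjusted p = 0.000795), SPP1 (edgeR adjusted p = 0.00172) and DDIT4L (2.35-fold; edgeR adjusted p = 0.0332). The 5 largest falls were the T cell receptor genes TRBV3-1 (3.15 CPM on TiB2, 0.0104 on the HA coating) and TRBC2 (17.1-fold lower), ITM2A (13.3 and 0.0617 CPM), TMEM160 (16.2-fold) and CITED4. TRBV3-1 is one of the 22 genes that part the libraries, and it lay at 3.08 and 1.86 CPM in bare alloy replicates 2 and 3 and at 0 in replicate 1. Other named members of lists were HSPA1B (2.02-fold) and HSPA1A (1.97-fold) higher, and AKR1B10 (3.08-fold), ABCC2 (3.50-fold), CEBPD (3.11-fold) and CSF2 (4.34-fold) lower. With the library set as a term SPP1, TRBV3-1, ITM2A, TMEM160, CITED4, HSPA1B, HSPA1A, AKR1B10 and ABCC2 turned sign, with values given below. Of the 16 named calls 10 were kept in all 6 cases with 1 library left out, while DDIT4L was lost in 5, MMP1, CSF2, HSPA1A and HSPA1B in 4 each and CEBPD in 2.

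Of the lists, 12 passed camera and none of them passed with an estimated correlation. Interferon-stimulated genes were higher on the HA coating (camera adjusted p = 1.52e-18; adjusted p = 0.683 with an estimated correlation). Heat shock proteins were higher by a median of 0.51, with 2 of 17 up over all genes and 5 up and 1 down adjusted over the list alone (camera adjusted p = 2.58e-05; adjusted p = 0.683 with an estimated correlation). Also higher, with median and camera adjusted p, were nuclear-encoded oxidative phosphorylation (0.44 and 5.34e-05), G1 and S phase genes (0.21, 0.00132), G2 and M phase genes (0.24, 0.00295) and ribosomal proteins (0.35, 0.0149). With an estimated correlation the last 4 had adjusted p = 0.749, 0.749, 0.749 and 0.833. None of the members of these 4 lists passed edgeR over all genes, and 1, of the G1 and S phase list, did adjusted over the list alone. NRF2 genes were lower by a median of -0.36, with 2 of 22 down over all genes and 8 down and 1 up adjusted over the list alone (camera adjusted p = 5.34e-05; adjusted p = 0.683 with an estimated correlation). Glucocorticoid response genes were lower by -0.40, with 1 of 20 down and 3 adjusted over the list alone (camera adjusted p = 0.000166; adjusted p = 0.683 with an estimated correlation). Collagens were lower by -0.52, with 0 of 17 past edgeR's threshold by either adjustment (camera adjusted p = 0.000543). The Notch pathway was lower by -0.50, with 0 of 18 past it and 3 down adjusted over the list alone (camera adjusted p = 0.0011). Collagen processing was lower by -0.32, with 0 of 22 past it and 1 down adjusted over the list alone (camera adjusted p = 0.00132). Inflammatory genes were lower by -0.39, with 1 of 30 down and 5 down and 1 up adjusted over the list alone (camera adjusted p = 0.0129). With an estimated correlation these last 4 lists had adjusted p = 0.749. The inflammatory call was lost without TiB2 replicate 1 (median -0.22, camera adjusted p = 0.458) or TiB2 replicate 3 (-0.23, 0.131), and without HA replicate 1 (0.0571) or HA replicate 2 (-0.25, 0.0955). Both cell cycle calls were lost without TiB2 replicate 3 (G2 and M phase 0.16, 0.135; G1 and S phase 0.11, 0.117), collagen processing without HA replicate 2 (-0.19, 0.122), and oxidative phosphorylation without HA replicate 3 (0.16, 0.0922). Ribosomal proteins lost theirs without TiB2 replicate 2 (0.081) or HA replicate 3 (0.001, 0.544). With the call kept, the glucocorticoid median was -0.26 without HA replicate 2, the Notch median -0.32 without HA replicate 3 and the collagen median -0.83 without HA replicate 1. Under the GC and length offset the collagen call (median -0.24, camera adjusted p = 0.0523) and the ribosomal call (0.08, 0.932) were lost. With a mean FPKM of at least 5 the G1 and S phase (0.13, 0.0623) and ribosomal (0.27, 0.0745) calls were lost. With the library set as a term the calls of heat shock proteins (median 0.39, camera adjusted p = 0.162), the Notch pathway (-0.35, 0.254), inflammatory genes (-0.29, 0.336) and ribosomal proteins (0.18, 0.262) were lost. The other 23 lists did not pass, with camera adjusted p from 0.0765 to 0.979.

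Over all genes edgeR called 127 of 20086 genes (0.6%), 36 higher and 91 lower, 2417 at an unadjusted p under 0.05 and 501 with DESeq2. Without 1 library the count ran from 49 (without TiB2 replicate 1 or HA replicate 2) through 62 and 66 (TiB2 replicates 3 and 2) to 1224 (HA replicate 1). The HA and TiB2 libraries lay wholly on opposite sides of the 22 genes, and of the 127 genes 81 (63.8%) parted the bare alloy libraries in the same way. In 1 fit over all 9 libraries without a set term edgeR called 67 genes, 38 of them shared with the 127. With the library set as a term, which the bare alloy libraries alone allow, it called 14 genes, 3 of them shared with the 127. These 3 were POSTN (2.24, edgeR adjusted p = 0.0105), PDXP (2.70, 0.0426) and ENSG00000272916 (-2.65), while SPP1 stood at -0.14. Most of the other calls were small structural RNAs that were high in bare alloy replicate 1 alone. RN7SK lay at 214 CPM there, 1.41 and 0.444 CPM in replicates 2 and 3, and 0.247 to 1.95 CPM in coated libraries. What is particular to bare alloy replicate 1 thus enters every difference between HA coating and TiB2 fitted with that term. The correction for the set rests on that library against replicates 2 and 3, so part of the fall in calls may be lost power. The other named genes that turned sign with that term were CITED4 (0.13), TRBV3-1 (2.29), ITM2A (4.50), TMEM160 (0.90), AKR1B10 (1.02), ABCC2 (1.87), HSPA1B (-0.17) and HSPA1A (-0.19).

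**Figure D5:**
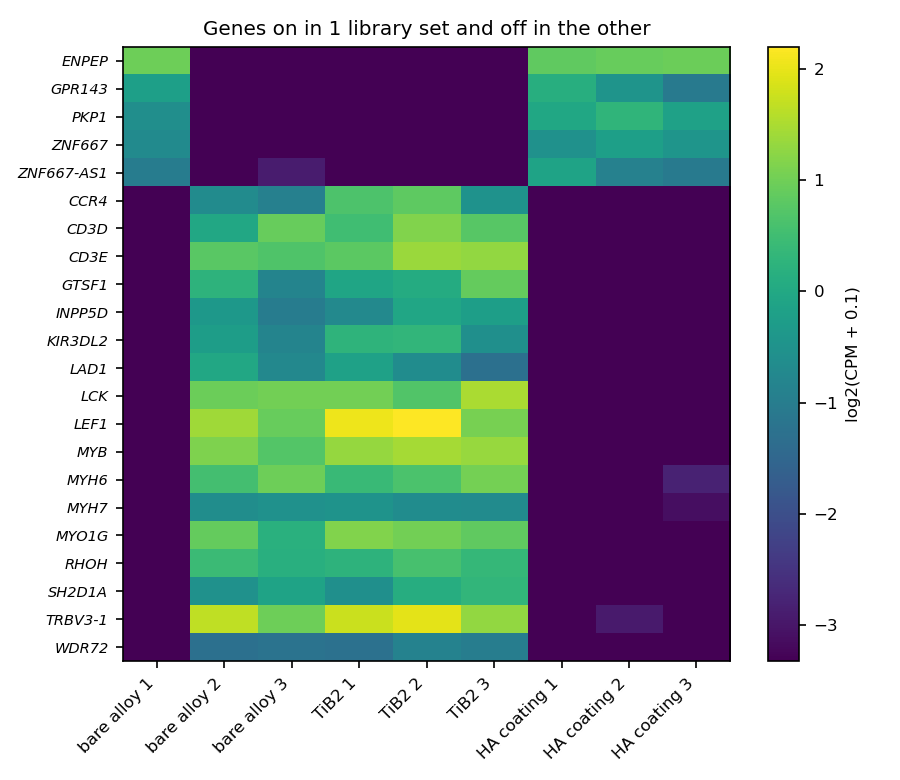
Levels of the 22 genes that part the libraries (rows) in each of the 9 libraries (columns), as log2(CPM + 0.1) on a colour scale. CD3E lay at 1.5 to 2.47 CPM in bare alloy replicates 2 and 3 and the TiB2 libraries and at 0 in the other 4, and ENPEP at 1.69 to 1.86 CPM in those 4.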

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

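The GC and length offset and the tests of the library sets were chosen after the data were seen, and the other tests in this part before their results were seen. Each list below stood out because the direct comparison of HA coating and TiB2 passed camera, so that the list's response differed between both coated surfaces. None passed with an estimated correlation, where adjusted p ran from 0.683 to 0.833.

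Interferon-stimulated genes were higher on the HA coating than on TiB2 by a median of 0.75 on the log2 scale, with medians of -0.26 and -0.83 against bare alloy. Under the GC and length offset the median was 0.62, and with 1 HA library left out at the lowest 0.60, each of which argues against that feature as the whole cause. With the library set as a term it was 0.66. The list's mean log2 level was 7.89, 7.86 and 7.79 in bare alloy replicates 1, 2 and 3. The HA and TiB2 libraries lie wholly on opposite sides of the set. The term thus rests on 1 bare alloy library against the other replicates, and cannot decide on the set. A difference between the surfaces therefore stays open as a hypothesis, beside the library set, and beside other differences between these libraries that were not tested. With the estimated correlation (adjusted p = 0.683) and with no member past edgeR's threshold over all genes, the difference itself is weakly supported.

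The inflammatory list had a median of -0.39 in the direct comparison, small beside 2.11 on the HA coating and 2.06 on TiB2 against bare alloy. For the rise on both surfaces, RNA of leukocytes in the coated cultures was tested through PTPRC, CSF1R, CD14, AIF1, ITGAM and LYZ, whose sum reached at most 7.11% of IL1B plus CXCL8 in any coated library. That share falls wherever IL1B and CXCL8 rise, whatever the cause. The sum itself, mostly CD14, overlapped, at 11.1 to 14.2 CPM on bare alloy and 6.93 to 16.0 CPM in the coated libraries. CD14 alone lay at 10.4 to 13.2 CPM on bare alloy, so a small rise of the other genes would not show in the sum. Of those, ITGAM was higher on TiB2 (0.28 to 0.41 CPM) than on bare alloy (0 to 0.094). PTPRC, CSF1R and AIF1 overlapped between these surfaces, and LYZ was 0 on both. The list's rise was 2.14 under the GC and length offset and 2.21 against bare alloy replicate 1 alone, the library that shares a set with the HA libraries. The medians of 2.14 and 2.21 argue against the GC and length trends and the library sets as the whole cause. Neither the share nor the sum can decide on leukocyte RNA. A response of the cells to the coated surfaces is left as a hypothesis, and a difference in culture between bare and coated wells was not tested.

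Heat shock proteins differed by a median of 0.51 (0.45 on the HA coating and 0.15 on TiB2 against bare alloy). NRF2 and oxidative stress genes differed by -0.36 (0.64 and 0.87). Nuclear-encoded oxidative phosphorylation differed by 0.44 (0.59 and 0.19). Glucocorticoid response genes differed by -0.40 (0.18 and 0.57). Collagens differed by -0.52 (-0.98 and -0.63). The Notch pathway differed by -0.50 (-0.22 and 0.26). G1 and S phase genes differed by 0.21 (0.93 and 0.66). Collagen processing genes differed by -0.32 (-0.31 and -0.16). G2 and M phase genes differed by 0.24 (1.18 and 0.89). Ribosomal proteins differed by 0.35 (0.44 and 0.09). With 1 library left out, the median nearest to 0 was 0.38 for heat shock proteins, -0.29 for NRF2 genes, 0.16 for oxidative phosphorylation, -0.26 for glucocorticoid genes, -0.39 for collagens, -0.32 for Notch, 0.11 for G1 and S phase, -0.19 for collagen processing, 0.16 for G2 and M phase, 0.001 for ribosomal proteins and -0.22 for inflammatory genes. With the library set as a term the calls of heat shock proteins (0.39, camera adjusted p = 0.162), the Notch pathway (-0.35, 0.254), inflammatory genes (-0.29, 0.336) and ribosomal proteins (0.18, 0.262) were lost, and under the GC and length offset those of collagens (-0.24, 0.0523) and ribosomal proteins (0.08, 0.932).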

How the results depend on the processing

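The GC and length offset, the removal of 2 libraries together and both library set settings were chosen after seeing the data, the other alternatives before. Over all alternatives 84 counts stayed within 1.5 times and 49 moved further. Of the named genes' values 3022 kept their direction and side of the threshold, 355 lost the call, 3 gained it and 11 reversed, and for the lists these numbers were 676, 75, 0 and 1. Unless stated, the cause was not tested. No scaling moved the median of all genes by more than 0.1 on the log2 scale. Depth limits low genes: IBSP had 0 to 4 counts per library. SP7 had 24 counts in bare alloy replicate 1, 12 in TiB2 replicate 1 and 0 to 2 in the other libraries. At similar depth 2-fold changes were recovered in 31% (HA coating against bare alloy), 68% (TiB2 against bare alloy) and 34% (HA coating against TiB2) of simulated cases, with a biological coefficient of variation of 30.7%, 21.8% and 29.8%. The simulated changes were all in genes above a mean of 1 CPM, so these rates do not cover genes as low as SP7, IBSP and BGLAP.

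For HA coating against bare alloy (1990 genes), 1232 had at least a 2-fold change and 5488 an unadjusted p under 0.05. Without a filter edgeR called 1093 and with a mean FPKM of at least 5, which tests fewer genes, 950. The fit over all 9 libraries gave 3518, the GC and length offset 3668, DESeq2 3562 and limma on log2(TPM + 1) 1268. Without bare alloy replicate 1 and HA replicate 3 edgeR called 756, with the set term 704 and within the set 286, which has 1 bare library. Leaving out 1 library gave 598 to 4185 (857, 601 and 1092 without bare alloy replicates 1 and 3 and HA replicate 2). Of 19 lists 3 passed with an estimated correlation and 9 with fry, which called 11 in all. SPP1 reversed to -0.13 with the set term and -0.11 within the set, which for this comparison are the same contrast.

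For TiB2 against bare alloy (5059 genes), 1428 had at least a 2-fold change. With a mean FPKM of at least 5 edgeR called 2594 genes and 13 lists, over all 9 libraries 2132, limma on log2(TPM + 1) 2092 and the set term 1173, and leaving out 1 library gave 3685 to 4211. An estimated correlation left 1 list. Limma on log2(FPKM + 1) called 2450 genes higher and 1495 lower (62.1% higher against 51.3% with edgeR), with a pseudocount of 0.1 2427 and 1477, with 0.5 2439 and 1492, without trend 2410 and 1495, and robust 2537 and 1538. The share of limma calls that were higher moved with the scaling. It was 57.2% on log2(TPM + 1), 54.2% with median-ratio scaling and 50.5% with quantile normalization.

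For HA coating against TiB2 (127 genes), 2417 had an unadjusted p under 0.05. The count was 61 with a mean FPKM of at least 0.5, 35 without a filter, 13 with a mean FPKM of at least 5, 67 over all 9 libraries (28 higher and 39 lower, 41.8% higher against 28.3%), 208 with the offset, 501 with DESeq2 and 14 with the set term. Limma called 80 on log2(FPKM + 1), 63 and 69 with pseudocounts of 0.1 and 0.5, 75 with median-ratio scaling, 62 on TPM, 79 with quantile normalization, 75 without trend and 80 robust. Leaving out 1 library gave 49 to 1224 (66 and 62 without TiB2 replicates 2 and 3). An estimated correlation left 0 lists and fry 0, against 12. Without HA replicate 3 the ribosomal list stood at 0.001 with its test turned. With the set term, which rests on the bare alloy libraries alone, SPP1 reversed to -0.14, TRBV3-1 to 2.29, ITM2A to 4.50, TMEM160 to 0.90, CITED4 to 0.13, AKR1B10 to 1.02, ABCC2 to 1.87, HSPA1B to -0.17 and HSPA1A to -0.19.

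Libraries shared replicate numbers across surfaces, but same-numbered libraries did not deviate together (correlations -0.057 to 0.040). This gives no sign that the numbers pair them, though a small shared effect could be missed. With the replicate block edgeR called 1357, 3625 and 195 genes in the 3 comparisons, and with block and offset 2670, 4663 and 111.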

Other observations

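The tests of gene ontology terms, of the GC and length offset, of the library sets, of the genes lower in 5 libraries and of the aryl hydrocarbon receptor and PPAR targets were chosen after the result was seen, the others before. Among ontology terms, which no list had covered, proteasome genes were higher on the HA coating than on bare alloy, 17 of 61 with none lower (median 0.54, camera adjusted p = 1.17e-08), and so were rRNA processing genes, 23 of 159 (0.44, 1.18e-07). Genes of homophilic cell adhesion, largely cadherins, were lower, 22 of 116 on the HA coating with 1 higher (median -0.60, camera adjusted p = 9.17e-07) and 37 of 109 on TiB2 with 8 higher (-0.47, 3.49e-05). Genes of unsaturated fatty acid synthesis were higher on TiB2, 6 of 14 with 1 lower (0.74, 2.35e-06). With an estimated correlation no term passed camera in any comparison, and these terms had adjusted p = 0.776 on the HA coating and 0.801 on TiB2. The terms were not run under the GC and length offset, with a library left out or with the library set as a term.

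Other bone genes were chosen after their values were seen, and are given for the HA coating only. The largest log2 fold change in the osteoblast list was 4.11 on the HA coating and 4.06 on TiB2, so a rise of that size was not particular to the HA coating. On the HA coating BMP2, a bone-inducing growth factor, was higher than on bare alloy by 4.11 on the log2 scale and TNFRSF11B, the decoy receptor that restrains osteoclasts, by 2.95, while COL1A2 was lower (-2.14), as were DLX3 (-1.42) and CDH11 (-0.83), all past edgeR's threshold.

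CYP1A1, a detoxifying enzyme induced through the aryl hydrocarbon receptor, was chosen after its values were seen. It lay at 11.5 ± 1.99 CPM on bare alloy, 224 ± 21.7 on TiB2 and 72.2 ± 20.1 on the HA coating (SD, n = 3), with log2 fold changes of 4.28 and 2.64 against bare alloy and -1.65 between the coated surfaces (edgeR adjusted p = 3.09e-07, 0.000786 and 0.0115). On TiB2 the median of 8 other targets of the receptor was 0.56, with 5 of them higher, CYP1B1 by 2.03 and TIPARP by 0.68, and on the HA coating, where fewer genes passed in all (9.9% against 25.1%), the median of 10 was 0.55, with 2 of them higher, CYP1B1 by 1.2 and TIPARP by 0.55. The 10 include UGT1A6 (1.06) and SERPINB2 (2), neither past the threshold on the HA coating and neither tested on TiB2. Both medians thus cover different genes and cannot be used to compare the surfaces. Activation of the receptor is a candidate explanation.

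PLIN2, which coats lipid droplets, was higher by 3.06 on TiB2 and 2.70 on the HA coating, and FABP3, a fatty acid carrier, by 2.83 and 2.82. On TiB2 8 of 9 other PPAR target genes were higher (median 0.54), PDK4 by 1.86 and ANGPTL4 by 1.56, and on the HA coating 2 of 9 (median 0.44), with PDK4 at 1.08 and ANGPTL4 at 0.91 not past the threshold, so activation of PPAR target genes may account for part of the rise. Both genes were chosen after their values were seen.

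The 127 genes called between HA coating and TiB2 placed bare alloy replicate 1 at a median position of 1 on a scale between TiB2 (0) and HA (1), and replicates 2 and 3 at 0.057 and 0.118, so a library set shared by the HA libraries and bare alloy replicate 1 may account for many of these calls. RNA of T cells in the 5 other libraries was examined with 23 further T cell genes. The split had been chosen on the same counts, with T cell genes among its markers, so a rank among splits gives no p-value. The mean of the 23 genes was 0.90 log2 units higher in the 5 libraries, the highest of 126 splits (highest other 0.68). Yet TRAC, an abundant T cell transcript, lay at 0 in all 5 libraries and PTPRC at 0.554 against 0.319 CPM, and the 5 genes at 20 counts or more in the 4 libraries and at 3 or fewer in each of the 5 argue against added T cell RNA for that part. Stocks or lots of cells that differ between the libraries stay open and untested, as do batches that the labels do not record. HA replicate 1 correlated more with the TiB2 libraries (0.976) than with the other HA libraries (0.955), and under the GC and length offset the values were 0.976 and 0.971. Yet over 163 genes called under the offset between TiB2 and the other HA libraries, it lay at 0.659 from TiB2 (0) to HA (1). TiB2 libraries left out in turn lay at 0.013 to 0.031 on that scale, over 13 to 23 genes.

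Splitting the 6 libraries of a comparison in any other way gave at most 0 genes for HA coating against bare alloy (1990 in the real split), 1 for TiB2 against bare alloy (5059) and 2 for HA coating against TiB2 (127), by edgeR. In each case 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05.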
